A study of Mus musculus with 6 samples.

How the data were processed

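Adipose tissue RNA of KM mice was measured by RNA-seq in 6 samples, 3 from a control group and 3 from a group fed radix Angelica sinensis (RAS), the dried root of a plant used in Chinese medicine, at 10.00 g per kg of body weight. Per the labels' protocols, poly(A) RNA was enriched on oligo(dT) beads, fragmented, copied with random primers and made into TruSeq libraries for an Illumina HiSeq instrument. The series title speaks of mice on a high-fat diet, and the diet label of the control samples reads control. The fat depot, the sex, the age and the hour of collection are not given in the sources used here. The labels number the samples of each group from 1 to 3 and do not say whether each sample is 1 animal or a pool, so p-values measure the spread between these samples.

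The authors deposited 1 table of 19928 genes with a symbol, an NCBI gene number, an Ensembl identifier and a locus per gene. FPKM values (fragments scaled for transcript length and library size) per sample were used as the authors deposited them. TopHat2 2.0.9 and Cufflinks 2.1.1 are named in the submitters' processing notes. The genome build, the annotation and any filter are not given in the sources used here. The table's loci overlapped the GENCODE M21 gene (GRCm38) with the same Ensembl identifier for 99.67% of 18403 genes found there, and coordinates are printed as the table gives them, counted from 1. In the table, 4251 genes stood on a locus shared with at least 1 other gene. The labels name no strand-specific step, so reads of overlapping or antisense genes may be mixed.

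The authors' table also holds a per-gene count signal per sample, deposited after scaling: 99.35 to 99.44% of the values above 0 were whole multiples, within 0.02 of a read, of 1 value per sample, which was 0.911 to 1.06. Divided by that value, the libraries held 14.4 to 15.7 M assigned reads. The signal was not treated as raw counts, and no count model, edgeR included, was run. Columns whose names carry the group name that the treatment protocol gives to the RAS mice were taken as the RAS samples. The other numbered set of 3 was taken as the control samples by elimination, with the numbers as in the sample titles. A further 4 columns of values per group were not used.

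Genes with a mean FPKM of at least 1 over the 6 samples were tested, 12606 in all. The test was limma's moderated test (lmFit, then eBayes with a trend) on log2(FPKM + 1), RAS against control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are RAS minus control. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Of 41 lists (628 entries, 583 found in the table, older symbols matched through NCBI gene numbers), 32 had at least 5 tested members. The lists, tests, naming rule and alternatives were set before the data were examined, except where said. A list score is the mean over a list's tested members of the log2 value minus the gene's mean over the 6 samples.

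Named genes follow a fixed rule: the 10 genes with the smallest unadjusted p in each direction (the rule where too few genes pass), passing over unnamed gene models and immunoglobulin and T cell receptor segments; 17 genes set in advance; and up to 4 members of a described list, in order of their p; whether 2 or 4 were described was settled after the values were seen. Adgre1 is listed in the table under its older symbol Emr1. Genes named outside the rule are said to be so.

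On simulated data with the real gene means and spreads, 12606 genes, 5 runs and 200 changed genes per run, the gene test recovered 65.6% of log2 changes of 1 and 93.8% of log2 changes of 2, with 7.8 false calls per run. The simulated list test, over 20 runs of lists of independent genes, found 100% of lists shifted by 0.5 and made 0 false calls per run; the real lists hold correlated genes. Alternatives were another pseudocount (0.1), no minimum or a mean FPKM of at least 5, quantile normalization, median-ratio size factors, a robust variance model, sample weights, the replicate number as a block and each library left out. The scaled counts in place of FPKM, and control 1 and RAS 3 left out together, were added after seeing the data. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.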

Results

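Gene expression in adipose tissue was compared between 3 samples from control mice and 3 from mice fed RAS at 10.00 g per kg of body weight. The series title asks about an anti-obesity effect of the root and the genes behind it. Each library held 14.4 to 15.7 M assigned reads and 12462 to 12641 genes at 1 FPKM or more. Scd1, the stearoyl-CoA desaturase of fat cells, took the largest share of the count signal in every library, 2.76 to 7.00%. Xist, the noncoding RNA of the inactive X chromosome (named outside the rule), lay at 35.7 to 67.5 FPKM in the 6 libraries.

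The libraries resembled each other closely. The mean correlation of log2 values was 0.972 within groups and 0.968 between groups. Single pairs overlapped: control 1 stood at 0.973 with RAS 1 and at 0.969 with control 2. The first principal component held 31.0% of the variance and set RAS 3 (34.5) against control 1 (-24.4), with the other libraries between -8.36 and 1.20. The second held 24.9% and placed the RAS libraries at 4.62 to 12.8, control 1 at 16.1, and controls 2 and 3 at -16.3 and -26.6.

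With RAS, clock genes differed in opposite directions, with the activators Arntl and Clock lower and Nr1d1 and Nr1d2 higher. Ccl2, Pnpla3 and Lep were lower and Pck1 higher in every RAS library. Means were higher for 17 of 18 genes of fat oxidation and 36 of 36 of the respiratory chain, and lower for 20 of 23 matrix and 15 of 18 cholesterol synthesis genes. The calls of these lists were lost with an estimated correlation (adjusted p 0.720 to 0.831), and their medians moved when RAS 3 or control 1 was left out. In the fat oxidation and respiratory chain lists, control 1 scored above RAS 1 and RAS 2. No single gene passed the test. In the limma comparison, 0 of 12606 genes had an adjusted p under 0.05 (smallest 0.138), and 1294 had an unadjusted p under 0.05, where 630 would be expected by chance. Of the 1294, 486 were higher and 808 lower with RAS; after division by median-ratio size factors the split was 684 against 623, so it depended on the scaling. The scaled counts gave 0 genes as well, with 1303 at an unadjusted p under 0.05. The FPKM ranges of the groups did not overlap for 2256 genes (17.9%; chance gives 10%).

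None of the 10 genes with the smallest p on the higher side was past the threshold. Slc27a1, a fatty acid transport protein, was at 122 ± 25.6 FPKM in control and 314 ± 45.6 with RAS (SD, n = 3 each, as below), a log2 difference of 1.36 ± 0.20 (SE). Rbp7, a retinol-binding protein of fat and its vessels, was at 253 ± 63.1 and 801 ± 155 (log2 1.67). Acot4, a peroxisomal acyl-CoA thioesterase with close paralogs beside it, was at 2.03 ± 0.27 and 6.43 ± 1.14 (log2 1.29), and Acsm5, a mitochondrial acyl-CoA synthetase, at 4.32 ± 0.86 and 9.26 ± 0.16 (log2 0.96). Niacr1, the niacin receptor that restrains lipolysis, was at 10.7 ± 1.07 and 21.1 ± 2.35 (log2 0.92). The other genes of the 10 were Metap1d (log2 1.00), Fbxo21 (1.35), the aquaporin Aqp11 (1.20), the transporter Slc16a12 (1.52) and the BMP inhibitor Smad6 (0.94). Their adjusted p values in limma ran from 0.138 to 0.197, and each was higher in 3 of 3 RAS libraries than in any control library. Choosing genes by their p in the same comparison largely builds in such separation, so it adds no support.

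On the lower side, Ccl2, the chemokine that draws monocytes (NCBI gene 20296; chromosome 11, 82035577 to 82037452), was at 4.25 ± 0.05 FPKM in control and 1.67 ± 0.14 with RAS, a log2 difference of -0.97 ± 0.11 (SE; limma adjusted p = 0.138). The neighbouring and similar chemokine gene Ccl12 was at 3.20 ± 0.20 and 1.14 ± 0.35 (log2 -0.98), and reads shared between them cannot be separated here. Ccl2 rested on 16 reads in its lowest library, so counting noise limits its precision. Its control SD of 0.05 is itself uncertain at n = 3. Pnpla3, a lipid droplet acyltransferase and lipase of the lipogenic programme, was at 163 ± 73.9 and 37.3 ± 7.93 (log2 -2.03). Oxtr, the oxytocin receptor, was at 46.1 ± 8.98 and 13.0 ± 4.82 (log2 -1.79), and Creb3l1, a transcription factor of secretory and matrix genes, at 12.6 ± 1.36 and 4.50 ± 0.88 (log2 -1.31). Popdc2 (log2 -1.03), the podosome adaptor Sh3pxd2b (-1.09), the proteoglycan-cleaving protease Adamts15 (-1.07), the splicing factor Sfpq (-0.70) and the angiogenesis inhibitor Vash1 (-0.86) completed the 10. Their adjusted p values ran from 0.138 to 0.196, and each was lower in every RAS library than in any control library, which again follows largely from the choice by p.

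**Figure D1:**
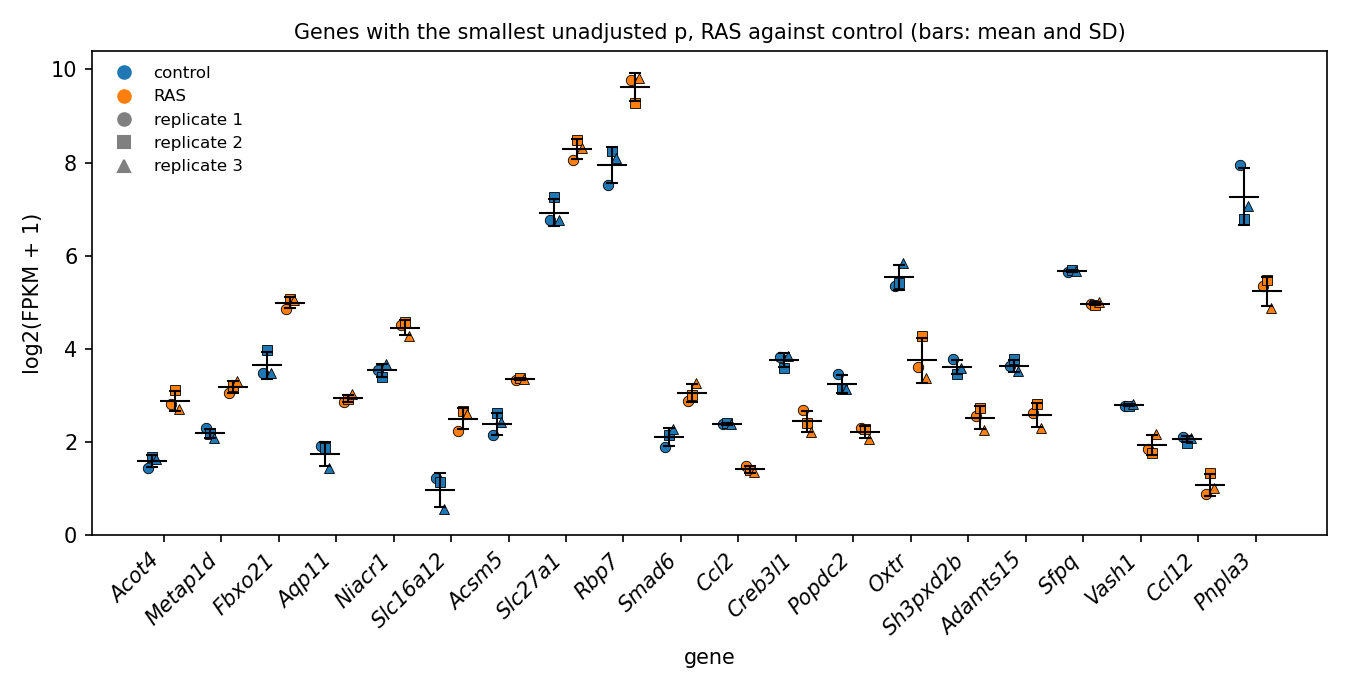
Log2(FPKM + 1) of the 10 genes with the smallest unadjusted p in each direction, 1 point per library (blue control, orange RAS, shape by replicate number), with bars at the mean and SD. The groups do not overlap for any of these genes, from Pnpla3 (log2 difference -2.03) to Rbp7 (1.67), and none has an adjusted p under 0.05. The lack of overlap follows largely from choosing the genes by p in this comparison.

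The circadian clock list held the most members past the threshold adjusted over the list alone. That adjustment is made within each list and not across the 32 lists. Of 15 tested members, 11 were higher and 4 lower; 0 passed over all genes and 9 passed adjusted over the list alone, 7 higher and 2 lower. Arntl, the activator at the core of the clock (NCBI gene 11865; chromosome 7, 113207465 to 113314126), was at 5.41 ± 2.55 FPKM in control and 0.849 ± 0.311 with RAS (log2 -1.72 ± 0.31). Its partner Clock was at 11.3 ± 2.55 and 6.59 ± 0.638 (log2 -0.68). The repressors Nr1d2 and Nr1d1, which are driven by that pair, were at 10.8 ± 4.81 and 28.7 ± 4.20 (log2 1.40) and at 18.0 ± 7.03 and 49.6 ± 16.8 (log2 1.42). Adjusted over all genes these were 0.240 to 0.283 in limma. Camera called the list higher (adjusted p = 0.00028; median log2 0.52), but the adjusted p was 0.720 with an estimated correlation. The number past the threshold over the list alone was 2 without RAS 2 and 3 without RAS 1, while the mean log2 value of the 13 other members minus that of Arntl and Clock differed between groups by 1.78 and 1.96 there, against 1.94 with all libraries.

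**Figure D2:**
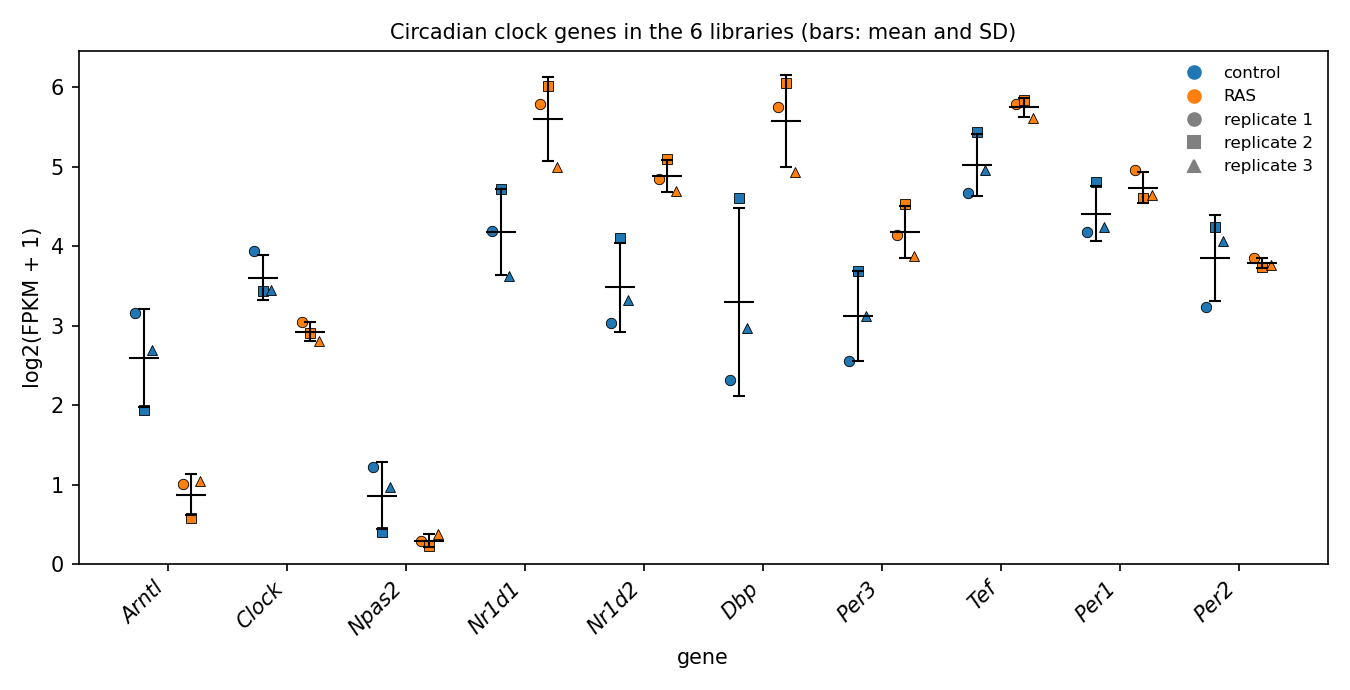
Log2(FPKM + 1) of 10 clock genes per library (blue control, orange RAS, shape by replicate number), with bars at the mean and SD; the genes beyond the fixed rule were chosen after their values were seen. Arntl (log2 difference -1.72) and Clock (-0.68) lie lower in every RAS library, Nr1d1 (1.42) and Nr1d2 (1.40) higher, and Per2 (-0.06) overlaps.

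Genes of heat production had higher means with RAS, with a list score of 1.89 in RAS 3 and at most 0.40 in any other library. The 0.40 belonged to control 1, above RAS 1 (-0.35) and RAS 2 (-0.02). All 11 tested thermogenic genes had a positive log2 difference (median 0.83; camera adjusted p = 0.0014, and 0.720 with an estimated correlation). Cidea, a lipid droplet protein of brown fat, was at 20.1 ± 20.7 FPKM in control and 110 ± 94.1 with RAS (log2 2.86), Cox7a1 at 36.2 ± 28.7 and 83.2 ± 78.6 (log2 1.05), and Kcnk3 at 14.4 ± 6.52 and 19.6 ± 1.71 (log2 0.49). Elovl3 was at 13.8 FPKM in RAS 3 and at 0.029 to 0.617 elsewhere. Ucp1, the uncoupling protein of brown and beige fat, was at 163 FPKM in RAS 3, 4.90 and 4.48 in RAS 1 and 2, and 33.8, 13.9 and 0.034 in controls 1, 2 and 3 (log2 1.10, limma adjusted p = 0.843). No member passed the gene test, also when adjusted over the list alone.

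All 36 nuclear genes of the respiratory chain had a positive log2 difference (median 0.29; camera adjusted p = 6.4e-08, and 0.831 with an estimated correlation), led by Cox7c (log2 0.46) and Ndufa4 (0.48). Of 18 fatty acid oxidation genes 17 did (median 0.32; camera adjusted p = 3.0e-06, and 0.720 with an estimated correlation). Ppara, the nuclear receptor that drives fat oxidation, was at 1.82 ± 0.627 and 3.63 ± 0.719 FPKM (log2 0.73), the carnitine carrier Slc25a20 at 29.1 ± 5.77 and 50.3 ± 13.9 (log2 0.75), Hadha at 67.8 ± 25.8 and 92.6 ± 12.7 (0.50) and Ehhadh at 14.7 ± 5.79 and 22.8 ± 7.51 (0.61). No member of either list passed over all genes or adjusted over the list alone. Control 1 scored above RAS 1 and RAS 2 in both (respiratory chain 0.26 against 0.09 and -0.09, oxidation 0.23 against 0.04 and 0.06). The FPKM ranges of the groups were apart for 0 of the 36 respiratory chain genes. Without RAS 3 the medians were 0.33 (thermogenic), 0.13 (respiratory chain) and 0.22 (oxidation), and without control 1 they were 1.48, 0.49 and 0.54.

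**Figure D3:**
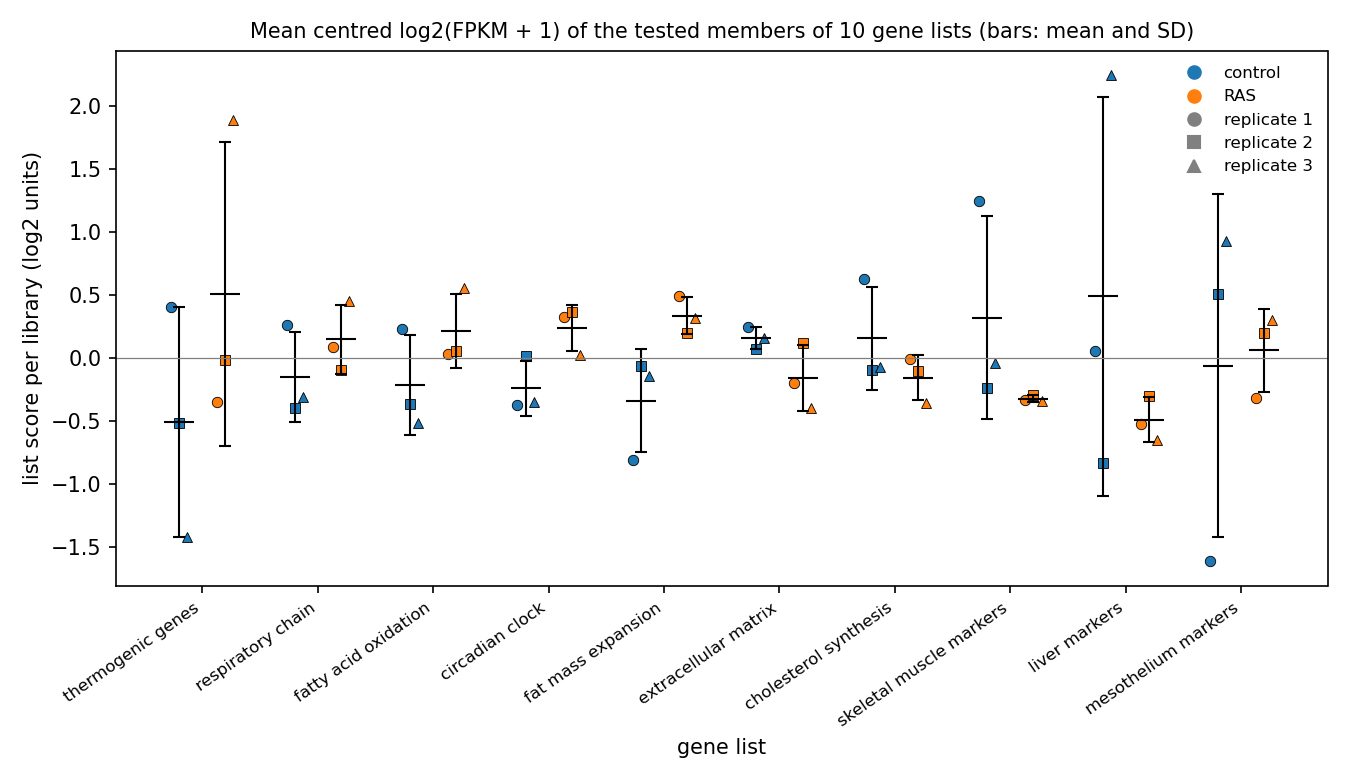
List score per library (mean of centred log2(FPKM + 1) over tested members, log2 units) for 10 gene lists, 1 point per library (blue control, orange RAS, shape by replicate number), with bars at the mean and SD. RAS 3 stands at 1.89 for thermogenic genes, control 1 at 1.24 for skeletal muscle markers and -1.61 for mesothelium markers, and control 3 at 2.25 for liver markers.

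Among mature adipocyte genes, 13 of 20 were higher and 7 lower, and the list did not pass (camera adjusted p = 0.071; its median of 0.10 turned to -0.00 under quantile normalization). Pck1, the cytosolic phosphoenolpyruvate carboxykinase that feeds glycerol synthesis (NCBI gene 18534; chromosome 2, 173153073 to 173159254), was the member past the threshold adjusted over the list alone: 564 ± 42.6 FPKM in control and 1216 ± 131 with RAS (log2 1.10 ± 0.18; limma adjusted p over all genes = 0.197). That call over the list alone did not hold in every alternative. Lep, the satiety hormone leptin (NCBI gene 16846; chromosome 6, 29060221 to 29073876), was at 424 to 615 and 293 to 334 (log2 -0.63 ± 0.19; adjusted p = 0.369), lower in 3 of 3 RAS libraries. Fabp4 was at 23034 ± 2999 and 37958 ± 7713 (log2 0.71), and Cidec at 1776 ± 214 and 2355 ± 209 (log2 0.41). Adipoq (log2 0.22), Pparg (0.12), Cebpa (0.01) and the glucose transporter Slc2a4 (0.09) differed by less than their SE.

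Of 8 genes tied to fat mass expansion, 5 were higher and 3 lower, with 0 past the threshold over all genes. Mest was at 19.1 ± 4.56 FPKM in control and 94.3 ± 49.6 with RAS (log2 2.08) and Sfrp5 at 33.8 ± 21.6 and 107 ± 32.5 (1.84), while Lep lay lower; these passed adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.083).

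Genes of fatty acid and triglyceride synthesis went both ways, 11 higher and 10 lower of 21 (camera adjusted p = 0.135). Besides Pnpla3, the member past the threshold over the list alone, Acacb was at 21.5 ± 12.3 and 47.7 ± 6.69 FPKM (log2 1.24), Dgat1 at 111 ± 18.2 and 159 ± 12.8 (0.53) and Acsl1 at 439 ± 82.6 and 741 ± 214 (0.73). Fasn was at 1249 FPKM in control 1 against 237 and 241 in the other controls and 411 to 1076 with RAS. Scd1 (log2 0.56) and Srebf1 (-0.29) had adjusted p values of 0.650 and 0.742. In lipolysis, 10 of 15 members were higher (camera adjusted p = 0.023, and 0.720 with an estimated correlation), among them Aqp7 (log2 0.50), Pde3b (0.34) and the triglyceride lipase Pnpla2 (0.42); Lipe stood at 0.13. That list's median of 0.13 was -0.01 under quantile normalization, and its call was lost there and without control 2, control 3, RAS 1 or RAS 2. Members that promote lipolysis and members that restrain it, Pde3b among the latter, were not separated. The direction of the list therefore does not give the direction of lipolysis.

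Cholesterol synthesis genes were lower in 15 of 18 cases (median -0.33; camera adjusted p = 0.021, and 0.831 with an estimated correlation): Cyp51 7.34 ± 2.79 and 3.99 ± 0.551 FPKM, Srebf2 11.3 ± 1.02 and 8.65 ± 1.32, Sqle 5.34 ± 2.22 and 3.09 ± 0.483, and Sc5d 27.8 ± 11.4 and 16.6 ± 3.72. None passed over the list alone, and the call was lost without control 1 (adjusted p = 0.386), without RAS 3 (0.302), without both (0.869) and with sample weights (0.454). In insulin and glucose handling, 9 members were higher and 9 lower (camera adjusted p = 0.922). Adjusted over the list alone, 3 of 18 passed: Foxo1 (log2 -0.56) and the PI3-kinase subunit Pik3r1 (-0.91) on the lower side and the kinase-like Trib3 (0.53) on the higher, while Ptpn1 (-0.30) did not. In fry's test of direction 0 of 32 lists passed (adjusted p at least 0.720). The mixed test of fry, which asks whether members differ in either direction, gave an adjusted p of 0.012 for this list and for mature adipocyte genes, 0.016 for nerve and Schwann cell markers, 0.00051 for cytokines and chemokines and 0.078 for the clock.

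Of 18 tested cytokine, chemokine and acute phase genes, 8 were higher and 10 lower (camera adjusted p = 0.540), and 2 passed adjusted over the list alone: Ccl2, above, and Nos2, the inducible nitric oxide synthase, at 2.83 ± 0.597 and 1.15 ± 0.306 FPKM (log2 -0.83). Cxcl10 (log2 -0.35) and Ccl7 (-0.46) did not pass. Tnf (0.227 ± 0.084 and 0.123 ± 0.001 FPKM) and Il6 (0.049 to 0.257 FPKM over the libraries) lay under the minimum of 1 and were not tested. Emr1, the macrophage marker F4/80, was at 14.4 ± 1.71 and 15.8 ± 1.70 (log2 0.13), and 14 of 21 macrophage markers were higher (camera adjusted p = 0.123).

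Extracellular matrix genes were lower in 20 of 23 cases (median -0.34; camera adjusted p = 0.0044, and 0.720 with an estimated correlation). Loxl2 was at 19.2 ± 0.511 and 14.2 ± 2.44 FPKM, Col5a1 at 36.5 ± 9.52 and 22.1 ± 5.76, Thbs1 at 101 ± 45.8 and 49.1 ± 8.77, Tnc at a log2 difference of -0.55, and Col1a1 at 137 ± 46.2 and 106 ± 44.8. Smooth muscle and pericyte markers were lower in 9 of 10 cases (median -0.55; adjusted p = 0.021, and 0.720 with an estimated correlation), with Acta2 at 192 ± 35.9 and 132 ± 11.8 and Des at 31.4 ± 11.4 and 19.7 ± 1.21. No member of either list passed over the list alone. Without RAS 3 the adjusted p was 0.125 for the matrix list (0.181 without RAS 3 and control 1) and 0.302 for the smooth muscle list, and for the latter 0.137 without control 2.

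Hypoxia-induced genes were higher in 9 of 11 cases (camera adjusted p = 0.023, and 0.720 with an estimated correlation), with Vegfa at 61.7 ± 2.31 and 104 ± 23.6 FPKM and Pdk1 at 7.46 ± 3.59 and 10.5 ± 2.79; the call was lost without control 2 or RAS 3, with no minimum FPKM (0.171) and under quantile normalization (0.122). Heat shock and unfolded protein genes were lower in 13 of 15 cases (adjusted p = 0.049, and 0.831 with an estimated correlation), with Hspa5 at 206 ± 37.4 and 135 ± 19.7 and Sdf2l1 at 16.6 ± 3.59 and 11.2 ± 2.74; the call was lost without control 2, control 3, RAS 1 or RAS 2 and with a pseudocount of 0.1 (0.0644). Red blood cell genes were higher in 5 of 5 cases (adjusted p = 0.0018, and 0.720 with an estimated correlation): Beta-s at 229 ± 109 and 478 ± 188 and Hba-a1 at 437 ± 106 and 844 ± 406, both from families of near-identical copies. Ribosomal protein genes were called higher (adjusted p = 0.023, and 0.831 with an estimated correlation) with a median of 0.08 that became -0.07 under quantile normalization and -0.10 without RAS 3, and the call was lost in 7 of 16 alternatives; Rps18 (197 ± 16.5 and 447 ± 197 FPKM) and Rpl32 (log2 0.27) have many processed copies in the genome, so their values are uncertain.

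Among markers of other cell types, endothelial genes were split 8 higher and 6 lower (camera adjusted p = 0.537); Eng (log2 0.56) passed over the list alone and Tie1 (-0.32) did not. Liver markers were lower in 7 of 8 cases (adjusted p = 0.242): Alb was at 88.4 FPKM in control 3 and 6.51 to 14.6 elsewhere, Apoa2 at 36.5 in control 3 and 2.54 in control 1, and listed at 0 in the other libraries, and Apoa1 at 18.3 in control 3 and 0 to 0.757 elsewhere, whereas Cyp2e1 was at 649 ± 20.7 and 1181 ± 469. Skeletal muscle markers were lower in 6 of 7 cases (adjusted p = 0.165). Acta1, skeletal actin, was at 127 ± 56.9 and 38.4 ± 19.5 FPKM (log2 -1.71) and passed over the list alone. In 12 of the 16 alternatives no muscle gene did, among them no minimum FPKM, quantile normalization and median-ratio size factors, while the log2 difference of Acta1 lay between -2.11 and -1.36. Tnni2 was at 5.70 in control 1 and 0.135 to 0.521 elsewhere, and Tnnc2 at 2.33 ± 3.19 and 0.353 ± 0.087, also highest in control 1. Eno3, the muscle enolase, was the member on the higher side (log2 0.21).

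The remaining lists did not pass camera. Higher and lower members numbered 4 and 9 for fibroblast and preadipocyte markers (adjusted p = 0.143), 3 and 9 for cell division (0.161), 1 and 5 for mast cells (0.255), 1 and 7 for B and plasma cells (0.394), 9 and 5 for NRF2 and aryl hydrocarbon receptor targets (0.394), and 6 and 4 for mesothelium (0.483). They numbered 6 and 8 for interferon-stimulated genes (0.559), 2 and 3 for T and NK cells (0.606), 4 and 6 for glucocorticoid-induced genes (0.745), 3 and 11 for immediate early genes (0.821) and 2 and 4 for nerve and Schwann cells (0.865). Camera's direction was higher for the interferon, T and NK cell and glucocorticoid lists, whose medians were -0.04, -0.01 and -0.09. Too few members to test were above 1 FPKM for neutrophil (4), mammary and other epithelium (4), lymphatic (3), ovary and uterus (3), skin (2), testis and epididymis (1) and pancreas markers (0). Mitochondrially encoded and Y-linked genes were not analysed here.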

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

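Of the alternatives, the scaled counts in place of FPKM and the joint omission of control 1 and RAS 3 were chosen after seeing the data. The alternatives set for raw counts were not run, because the values used are not raw counts. No gene passed under the pseudocount, filter, scaling, robust, weighted and scaled-count alternatives. With 1 library left out, genes past the threshold numbered 0 to 2, of which 0 to 1 higher and 0 to 2 lower. Without control 1 these were Gm19601 and Gm6293, without RAS 1 H2-T9 and without RAS 2 Cd1d2 (higher), all outside the naming rule and named after their values were seen. Without control 1 and RAS 3 together, 3 genes passed, 3 of them lower: Gm19601, Gm6293 and Gm5526 (also outside the rule and named after its values were seen). Genes at an unadjusted p under 0.05 numbered 987 to 1367 with 1 library left out, 1692 with no minimum, 911 at a mean FPKM of at least 5, 1850 with sample weights and 1740 without control 1 and RAS 3.

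The replicate numbers were not taken to pair the samples: same-numbered libraries deviated from their group means with correlations of 0.178, 0.096 and 0.219, 1 of them under 0.1. Every library did correlate best with its own number, a hint from the data that the labels do not speak to. With the number as a block, 0 genes passed, 1663 had an unadjusted p under 0.05, and 12 lists passed, all 12 the same lists.

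Lists past the threshold numbered 9 to 16 over the alternatives, against 12. Every alternative kept camera's preset correlation of 0.01, so these counts do not speak to that choice. With an estimated correlation, or in fry's test of direction, 0 of 32 lists passed. Calls kept in all 16 alternatives were those of the respiratory chain, fatty acid oxidation, thermogenic and clock lists; the red blood cell list kept 15, the matrix and smooth muscle lists 14, cholesterol synthesis and hypoxia 12, lipolysis and heat shock 11, and ribosomal proteins 9. The ribosomal list turned lower under quantile normalization (median log2 -0.0703), with sample weights (-0.0770), without RAS 3 (-0.10) and without control 1 and RAS 3 (-0.15), where cholesterol synthesis also turned (camera's direction higher, median -0.0162); without control 3 the ribosomal median was 0.25. Members past the threshold over the list alone numbered 2 to 13 over the alternatives for the clock, 0 to 2 for mature adipocyte, 0 to 4 for fat mass, 1 to 13 for fat synthesis, 0 to 4 for insulin, 0 to 5 for cytokine and 0 to 1 for endothelial and for muscle genes. Of 1470 values of 93 named genes, 1457 kept direction and side. No named gene passed in the main fit and 0 values passed only under an alternative, so this count reflects direction alone. Sizes could move widely, as for Elovl3 (0.48 to 3.73) and Fasn (0.37 to 1.95). Reversed were Pparg without control 3 (-0.0855; 0.37 without control 1); Cebpa without control 3 (-0.0918; 0.12 without control 1), under quantile normalization (-0.15) and with scaled counts (-0.02). Slc2a4 reversed without control 2 (-0.0421) and control 3 (-0.0946; 0.40 without control 1), and Ucp1 without control 3 (-0.38) and RAS 3 (-0.51; 2.15 without control 1). Lipe reversed under quantile normalization (-0.0513), and Srebf1 (0.18), Col1a1 (0.0236) and Eno3 (-0.0307) without control 1 and RAS 3. Fabp4 came to 0 under quantile normalization, which by construction gives the top gene of every library 1 value. The cause of the other reversals was not tested. Mean correlation was higher within than between groups in every setting computed (difference 0.00189 to 0.00801). Depth limits low genes: Ccl12 rests on 4 reads in its lowest library, Ccl2 on 16, Ucp1 and Elovl3 on 1.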

Other observations

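The ribosome biogenesis and SRF tests below were set after Heatr1, Pwp2 and Srf had been seen but before the lists were looked at; the PPARG test was chosen only after its result was seen. Factors that build ribosomes had lower means with RAS in most cases, without passing the test over all genes. Outside the naming rule and after their values were seen, Heatr1 (4.48 ± 0.05 FPKM in control and 2.48 ± 0.30 with RAS, SD) and Pwp2 (5.17 ± 0.19 and 3.20 ± 0.14) were noticed with Tsr1, Rrp12 and Nat10 among the genes with small p values; all 5 act in ribosome assembly. The hypothesis that other ribosome biogenesis factors are lower too was tested on 40 further genes, none of them in the fixed lists: 37 were lower and 3 higher, with a median log2 difference of -0.26. The largest median in the 9 other splits of the libraries was 0.17 in size, and with 1 library left out the median lay between -0.30 and -0.24. Adjusted over that list alone 6 passed, among them Nop56 (log2 -0.44) and Nop58 (-0.57), also outside the rule and named after their values were seen, and 0 passed over all genes. The 5 genes that prompted the list were noticed by their small p values in these same libraries. Genes that vary together with them would follow the same split, so the 40 genes are not an independent test. With 10 splits no share under 0.1 can be reached either, so a lower output of ribosome building may be proposed only as a hypothesis.

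Genes of the actin cytoskeleton showed a similar picture. Srf, the transcription factor of actin genes, named like the other SRF genes here outside the rule after its values were seen, was at 17.7 ± 2.15 and 9.14 ± 1.36 FPKM (log2 -0.88; limma adjusted p = 0.197). Of 22 other SRF target genes 20 were lower, with a median of -0.33 against 0.22 in size for the highest other split and a range of -0.43 to -0.25 with 1 library left out. Adjusted over that list alone 7 passed, among them Vcl (log2 -0.59), Flna (-0.75) and Actb (-0.67); none passed over all genes. Smooth muscle and pericyte markers, which share no gene with that list, were lower in 9 of 10 cases with a larger median of -0.55, and the SRF targets themselves include genes of smooth muscle such as Myl9 and Lmod1. Srf too was noticed in these same libraries, so target genes that vary together with it are not an independent test. Lower SRF activity and fewer smooth muscle cells are both candidate explanations, and they cannot be told apart here. For PPARG, prompted by Pck1, Rbp7, Slc27a1 and Niacr1, 25 of 29 other target genes were higher with a median of 0.29, but another split reached 0.34, so the hypothesis stays undecided; 21 of its 30 genes are also in the fixed lists.

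Of the tests on the clock genes, the count with 1 library left out was set beforehand; the others were chosen only after the result was seen. The log2 ratio of all 13 other tested clock genes to the activators Arntl and Clock, a split by role made after their values were seen, was 0.10 ± 0.73 in control and 2.04 ± 0.30 with RAS (SD), a difference of 1.94 with no overlap. The count set beforehand came out on the side of a single library: 2 clock genes stayed past the threshold over the list alone without RAS 2, under the bound of 4, though omission also removes degrees of freedom. The size, a test added afterwards, does not rest on a single library: at least 82.6% of the difference was left whichever library was omitted. As that ratio was split after the values were seen, it cannot overrule the count. Whether a single library is the source of the lost calls stays undecided. A different mix of cell types stays open. The difference is 3.48 times the SD within groups, under a bound of 4 that was chosen afterwards. The ratio does not measure cell types, which could differ in it, so no value of it could exclude a change in the mix. RAS itself also stays open, and so does another hour of collection or feeding, which could give such a difference, as the labels give no hours.

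For thermogenic and oxidative genes, in tests chosen only after the result was seen, brown adipocyte RNA in RAS 3 is a candidate source of part of the difference. Without RAS 3, 39.2% of the thermogenic median and 46.4% of the respiratory chain median were left. RAS 3 scored highest in both lists, so its omission would lower these medians whatever the source. The fall therefore does not single out brown adipocyte RNA. Ucp1 (163 FPKM), Cidea (218) and Cox8b (396, outside the naming rule) were highest in RAS 3, though the camera calls of both lists remained without it at the preset correlation (adjusted p = 0.045 and 0.0016). At an estimated correlation both calls are lost even with all libraries (0.720 and 0.831). The fatty acid oxidation median fell by a smaller share without RAS 3 (values given above). Whether RAS 3 had browned fat or a piece of another depot was not tested.

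The tests on liver and muscle markers were also chosen only after the result was seen. RNA of other tissues in single control libraries is a candidate source. Without control 3 the liver median was -0.25 in place of -1.14, and without control 1 the skeletal muscle median was -0.10 in place of -0.69. Control 3 scored highest for liver markers and control 1 for muscle markers, so their omission would shrink these medians whatever the source. These changes therefore do not single out RNA of other tissues. Acta1 differs from the other muscle genes: without control 1 its log2 difference was still -1.40, so muscle fibres in control 1 do not account for it. Cyp2e1 is also expressed by fat cells, and went the other way.

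The splits were chosen only after the counts were seen. Whether chance can be excluded cannot be settled with 10 splits, whose smallest share is 0.1. The real grouping gave 0 genes past the threshold (all 10 splits gave as many; highest other 4) and 12 lists (7 of the splits gave as many; highest other 23). It gave 1294 genes at an unadjusted p under 0.05, the highest count of the 10 splits, with 905 next (1 split as large, the real one).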
